A study of Homo sapiens with 4 samples.

How the data were processed

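The series holds 4 arrays of total RNA from CD34+ cells of human umbilical cord blood, 2 treated with 1,25(OH)D3 and 2 with DMSO vehicle. Per the labels' protocols, RNA was extracted with a micro-scale column kit and treated with DNase. It was labelled with an Affymetrix whole-transcript kit, and the cells had been kept for 4 h in serum-free medium. The deposited values are log2 signals of 70523 probe sets per array, and the submitters' processing notes name RMA and limma without a version. RMA corrects background, quantile-normalizes arrays and sums probes by median polish. Whether the normalization covered these 4 arrays alone, and at which probe level, is not given in the sources used here. The medians of the 4 arrays over all probe sets ran from 5.73 to 5.83, so the arrays are close to each other and not identical in distribution. For each array the precision rests on the number of arrays, and no read depth applies.

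Probe sets were named through the platform annotation given for this work, and symbols were updated through a RefSeq gene table of the assembly GRCh38.p14, used for names, gene types and chromosomes only. Of the 70523 probe sets, 23781 carried 1 gene symbol, 1543 carried several and 45199 were unnamed here. Of the 23781, 21497 matched by gene ID, 1974 by symbol, 306 by an older symbol and 4 not at all. The brightest probe set by the mean over all 4 arrays stood for each symbol, which gave 22411 genes, 528 of them with several probe sets to choose from. No coordinates are printed, because the sources used here do not name the build of the probe sets. XIST and Y-linked genes entered the fit and appear in no printed table.

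Treated arrays were compared with vehicle arrays in limma 3.58.1 under R 4.3.3, with lmFit and eBayes using a mean-variance trend, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The cord blood sample entered as a block, because the series text says that cells of one sample were split between hormone and vehicle and the titles carry the same sample and replicate number in both groups. As a check of the pairing, the difference between replicates in vehicle arrays correlated with that in treated arrays at r = 0.480 across genes. Direct correlations did not single out the partners in pair 1. DMSO 1 correlated with its own treated array at r = 0.990, with DMSO 2 at 0.994 and with treated array 2 at 0.992, while the arrays of pair 2 correlated at 0.998. The pairing therefore rests on the labels. The blocked fit leaves 1 residual degree of freedom, and limma's estimate of the prior degrees of freedom was infinite, so each gene's error was taken from the trend over genes of like signal and not from its own spread. The p-values therefore measure a typical spread, over genes of like signal, of the treatment change between the 2 pairs. Differences in level between the cord blood samples are removed by the block. Standard errors printed beside changes are those of this fit. Unless stated otherwise, an adjusted p beside a gene is limma's.

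Gene lists were tested with limma's camera at its preset correlation of 0.01, two-sided, with adjustment over 23 lists written before the data were examined. The lists hold VDR targets, inflammation, stress and metabolism genes, and markers of the cell types that a CD34+ fraction could contain. Listed genes without a probe set in the table of names were not analysed here. Counts adjusted over the list alone apply Benjamini and Hochberg within one list. No list kept its call with a correlation estimated from the data, an estimate that is poorly determined at 1 residual degree of freedom, or in fry. A list's median was also set against 10000 random lists matched on mean signal.

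Genes named in the text follow a rule fixed beforehand. It took CYP24A1, VDR, CD14, CAMP and CXCL8 in any case. It then took the 12 largest rises and 12 largest falls, ranked by the smaller of the changes of the pairs, among genes with the same sign in both pairs, an unadjusted p under 0.05 and a mean in the higher group at or above the median of all genes, 6.55. Symbols of uncharacterised loci and small RNAs were left out of that part. From each list it took up to 4 members with an unadjusted p under 0.05 and the same sign in both pairs.

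The fit was tested on simulated arrays of 22411 genes with 200 changed genes. It recovered 64.2% of genes changed by 0.25 on the log2 scale and 100% of those changed by 0.5 and by 1, with 9 false calls among 185. Without the block the shares were 0%, 7.46% and 93.9%. With 1 list shifted by 0.2, camera called that list and 0 of the 22 others. The simulation drew independent errors for each gene and so holds no array-wide shift. It also gave genes of like signal the same spread, which the fit itself assumes. Its rates therefore do not cover genes whose pairs differ by more than that. The simulated errors were scaled to the median over genes of the real residual SD. At 1 residual degree of freedom that median lies below the pooled SD of the real fit. The share recovered at 0.25 is therefore too high for the real arrays, where H3-4 at -0.29 did not pass (limma adjusted p = 0.0564).

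Alternatives set beforehand were the fit without the block, eBayes without trend or with robust estimation, removal of the dimmest 30% or 50% of genes, renewed quantile normalization, median centring, other choices of probe set, other thresholds, other list tests, and leaving out each array or pair. A loess correction on signal (span 0.4), protein-coding genes alone, and a required same sign in both pairs were added after seeing the data. Figures were drawn with matplotlib 3.10.9.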

Results

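RNA levels were measured on whole-transcript microarrays in CD34+ cells of human umbilical cord blood, the fraction that holds most of the hematopoietic stem and progenitor cells. Cells of 2 cord blood samples were each split and kept ex vivo for 4 h with 1,25(OH)D3 or with its solvent DMSO as vehicle. 1,25(OH)D3, or calcitriol, is the hormone form of vitamin D and the ligand of the nuclear receptor VDR. The 2 treated and 2 vehicle arrays form 2 pairs, called pair 1 and pair 2, and their number limits the precision of every value below. The labels give the dose as 1 mM, a figure that could not be checked here. Values are log2 RMA signals, changes are treated minus vehicle within a pair, and 22411 genes were tested with 1 probe set each.

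The study asked which genes lie downstream of vitamin D signalling in these cells. Treated cells differed from their own vehicle cells in 791 genes, of which 485 were higher and 306 lower. CXCL8, the neutrophil-attracting chemokine interleukin-8, rose by 0.30 on the log2 scale (SE 0.093), at 0.46 and 0.15 in the 2 pairs. Unless given after loess, SEs here and below come from the trend over genes of like signal, not from a gene's own 2 pairs. The interferon-induced antiviral genes RSAD2 and MX1 fell by 0.53 (SE 0.099) and 0.48 (SE 0.092), at -0.95 and -0.88 in pair 1 and -0.10 and -0.086 in pair 2. CYP24A1, which encodes the hormone's own degrading enzyme and is a classic VDR target, was at -0.019 (SE 0.088), which did not pass the test. Changes were small, with a median fold of 1.26 among the 791 genes, 13 genes at 1.5-fold or more (11 higher and 2 lower) and 1 at 2-fold or more.

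These counts come from limma with the cord blood sample as a block, at a Benjamini-Hochberg adjusted p under 0.05. Without the block limma gave 0 genes, with a smallest adjusted p of 0.402 and 2556 genes at an unadjusted p under 0.05 against 4604 with it, and 0 to 2 genes when any 1 array was also left out. After a further quantile normalization 16 genes were higher and 11 lower, in a fit whose prior degrees of freedom fell from infinite to 12.5. With each array centred on its median 79.7% of the called genes were higher against 61.3% in the values as deposited. At an unadjusted p under 0.05 in limma 13 genes passed at 1.5-fold, 1469 at 1.2-fold and 1 at 2-fold. The series text counts 407 differentially expressed genes without giving a threshold.

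Of 5 genes chosen beforehand, CXCL8 passed the test and CYP24A1, VDR, CD14 and CAMP did not. CXCL8 went from 7.64 ± 1.26 (SD, n = 2) with vehicle to 7.94 ± 1.05 with 1,25(OH)D3. It was higher in both pairs, by 0.46 and 0.15 (limma adjusted p = 0.040), and the 2 cord blood samples differed far more from each other, at 6.75 and 8.53 with vehicle. Among the 1000 genes nearest to CXCL8 in mean signal, its change stood at percentile 98.3 in pair 1 and 93.7 in pair 2. Without the block the adjusted p of CXCL8 in limma was 0.806, and with 1 array also left out its change ran from -0.59 (without vehicle of pair 1) to 1.195 (without vehicle of pair 2). CYP24A1 read 4.30 ± 0.030 (SD, n = 2) with vehicle and 4.28 ± 0.039 with hormone (limma adjusted p = 0.914), and its change of -0.019 became 0.051 after loess on signal. VDR, the receptor itself, was at -0.18 (SE 0.10; limma adjusted p = 0.299). CD14, a monocyte co-receptor and VDR target, was at 0.0067 (SE 0.11; limma adjusted p = 0.976). CAMP, which encodes the antimicrobial peptide cathelicidin and is a direct VDR target in human blood cells, was at -0.52 in pair 1 and -0.031 in pair 2 (limma adjusted p = 0.0750).

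**Figure D1:**
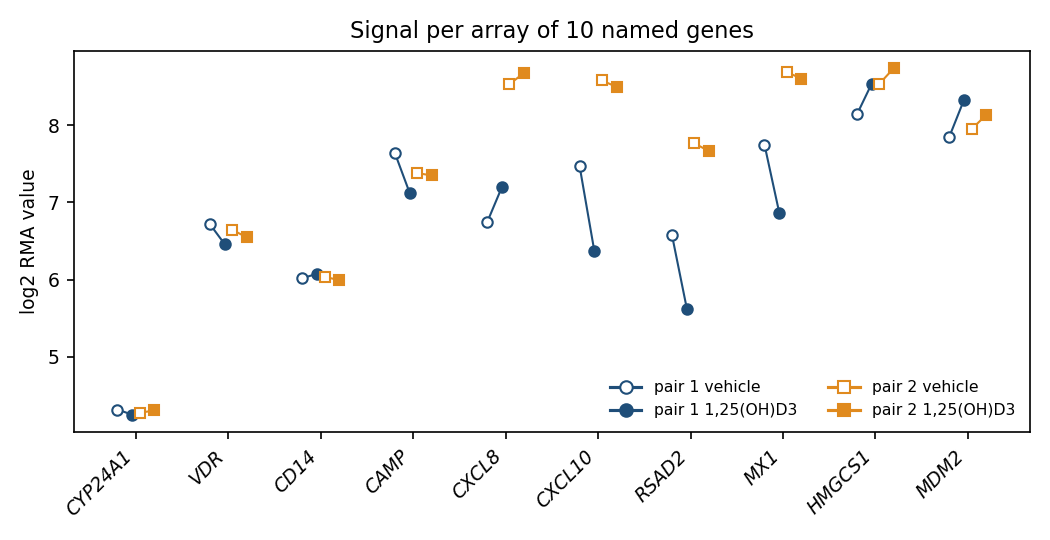
Log2 RMA signal of 10 named genes on each of the 4 arrays, with open symbols for vehicle, filled symbols for 1,25(OH)D3, and a line joining the arrays of a pair (circles, pair 1; squares, pair 2). CXCL8 was higher with hormone in both pairs, at 7.20 against 6.75 and at 8.68 against 8.53, while CYP24A1 lay between 4.25 and 4.32 on all 4 arrays.

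Within the signal and symbol limits of the naming rule, the largest rises shared by both pairs were led by IGHD3-3 and FANCF. FANCF, an adaptor of the Fanconi anemia DNA repair complex, rose by 0.57 (SE 0.099; limma adjusted p = 7.8e-06). The lysophosphatidylserine receptor GPR174 rose by 0.45, the splicing factor BCAS2 by 0.42, the mRNA cleavage factor CPSF2 by 0.42, the TFIID subunit TAF11 by 0.34 and the snoRNP assembly factor ZNHIT3 by 0.40. The membrane protein gene ITM2B rose by 0.37 and NDUFAB1, the mitochondrial acyl carrier protein, by 0.35. IGHD3-3, a short immunoglobulin diversity segment, rose by 1.07 (SE 0.10; limma adjusted p = 1.7e-21). SUMO4 rose by 0.44, and the pseudogenes FRG1HP and ROCK1P1 by 0.48 and 0.33. These 3 have close copies elsewhere in the genome, and signal from a copy was not checked here.

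Within the same limits, SMIM32 and CHRM4 led the shared falls. SMIM32, a small membrane protein gene, fell by 0.49 (SE 0.099; limma adjusted p = 2.6e-04) and the muscarinic receptor gene CHRM4 by 0.46 (SE 0.10; limma adjusted p = 0.00183). The eye homeobox gene RAX fell by 0.35, the beta-cell factor MAFA by 0.33, the tight junction gene CLDN9 by 0.37, KTI12 by 0.38 and the pseudogene FAAHP1 by 0.41, which became -0.24 with the mean over probe sets. FAAHP1 then did not pass (adjusted p = 0.160), nor did it at -0.38 after quantile normalization (0.129) or at -0.36 after loess (0.0571). The growth factor genes FGF3 and FGF6 fell by 0.37 and 0.39. The histone gene H3-4 (-0.29), the pre-B cell gene VPREB1 (-0.29) and ENTREP2 (-0.29) ranked among the 12 largest falls within these limits but did not pass, at limma adjusted p = 0.0564, 0.0683 and 0.0864. Negative control probe sets of like signal also fell. Those with 17 and 18 GC bases, at 6.73 and 7.35 on vehicle 1, changed by -0.37 and -0.34 in pair 1. In pair 2 they changed by -0.26 and -0.30. The GC content of the genes is not known here, so a background shift was not told apart from falls of these genes.

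Of the 98 named genes, 42 passed the test in limma. Without the block all 42 calls were lost, after quantile normalization 40, and after a signal-dependent loess correction chosen after seeing the data 28. Under each of the last 2, the changes of 39 of the 42 genes stayed within 1 SE of their first value. The prior degrees of freedom fell from infinite to 12.5 and 19.3, and with the error taken wholly from the trend, as in the first fit, 4 and 2 of the 42 calls were lost.

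Across all genes the changes of the 2 pairs correlated with Pearson's r = 0.499 and Spearman's rho = 0.529, and 74.4% of genes had the same sign. Genes are not independent replicates, so no p is attached. The spread of the changes differed between the pairs, with an SD of 0.22 in pair 1 and 0.11 in pair 2. Treated array 1 differed from its own vehicle and from the arrays of pair 2 by SDs of 0.22, 0.23 and 0.20, and the other 3 arrays differed among themselves by 0.11 to 0.21. A deviating array and a larger response were not told apart here. A total of 132 genes changed over 1.5-fold in pair 1 against 25 in pair 2, with 2 in both. Of the 791 genes, 783 had the same sign in both pairs. Median changes differed with signal, at 0.11 in pair 1 and 0.043 in pair 2 for the brightest decile of genes, and at -0.076 and -0.044 for the dimmest.

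**Figure D2:**
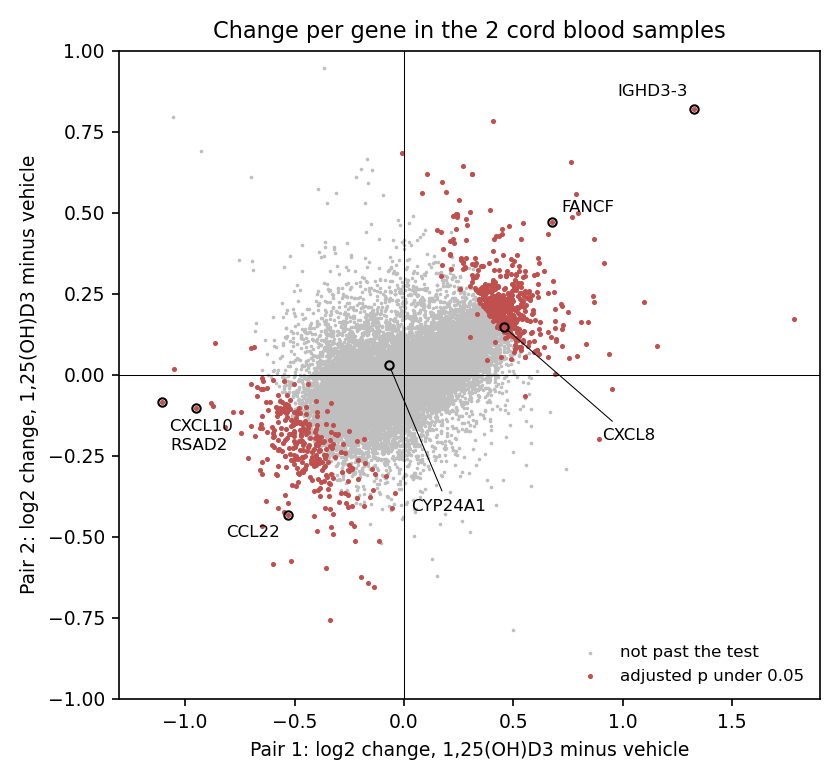
Log2 change of each gene in pair 1 (horizontal) against pair 2 (vertical), 1,25(OH)D3 minus vehicle, with grey points for genes that did not pass and red points for those at an adjusted p under 0.05. The changes of the pairs correlate at r = 0.499, with CXCL10 at -1.10 and -0.083, RSAD2 at -0.95 and -0.10, and CYP24A1 at -0.068 and 0.030.

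Known VDR targets gave 1 called gene in each of the lists for blood cells and for other tissues. Over all genes 791 of 22411 were called. Of 35 VDR targets of blood cells 1 rose and 34 did not pass, with the same count of 1 adjusted over the list alone and a median change of -0.070. SERPINB1, an inhibitor of neutrophil proteases, was the member that rose, by 0.35 (SE 0.091; limma adjusted p = 0.0120). Its change was 0.25 after loess on signal. TXNIP, an inhibitor of thioredoxin, had 0.24 and the nuclear receptor corepressor NRIP1 0.22 (0.062 after loess on signal), without passing. The list as a whole gave an adjusted p of 0.715 in limma's camera. Of 18 VDR targets of gut, kidney and bone 1 rose and 17 did not pass, again 1 adjusted over the list alone (median -0.094; camera adjusted p = 0.564). The member that rose was ATP2B1, a plasma membrane calcium pump, by 0.35 (SE 0.091; limma adjusted p = 0.0121). None of 16 receptor and metabolism genes passed in limma (4 at an unadjusted p under 0.05), and 0 did adjusted over the list alone (median 0.0074; camera adjusted p = 0.564). Among them were the hormone-activating enzyme gene CYP27B1 at -0.25 and the chaperone PDIA3 at 0.27, or 0.12 after loess.

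Interferon-stimulated genes were the list with the largest shift. Of 22 measured members 0 rose, 9 fell and 13 did not pass, and 17 fell adjusted over the list alone. RSAD2, MX1, OASL and IFIT3, all antiviral effectors, fell by 0.53, 0.48, 0.46 and 0.45. The list median was -0.27, and camera gave an adjusted p of 9.2e-11, against an adjusted p = 0.721 with an estimated correlation and 0.403 without the block. With 1 array also left out, the median ran from -0.82 (without treated array 2) to 0.37 (without treated array 1). Donor differences enter such fits. The shift was uneven, with a median of -0.39 in pair 1 and -0.088 in pair 2. Pair 1 had 21 members lower and 1 higher, and pair 2 had 15 lower and 7 higher. Of the 9 that fell, 3 were slightly higher in pair 2. These were IFI44L, IFIT1 and IFIT2, named after their values were seen, at 0.018, 0.099 and 0.085. Negative control probe sets with 12 or more GC bases also read lower in treated arrays, by a median change of -0.24 in each pair.

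Chemokines moved both ways. Of 28 chemokine and receptor genes 1 rose, 2 fell and 25 did not pass, and the counts adjusted over the list alone were also 1 and 2 (median -0.11; camera adjusted p = 0.108). Beside the rise of CXCL8, the interferon-inducible CXCL10 fell by 0.59 (SE 0.093; limma adjusted p = 3.0e-07), at -1.10 in pair 1 and -0.083 in pair 2. CCL22, a ligand of CCR4, fell by 0.48 (SE 0.11; limma adjusted p = 0.00141), at -0.53 and -0.43. Negative control probe sets with 16 GC bases, at 6.18 on vehicle 1 against 6.17 for CCL22, changed by -0.36 and -0.21. The GC content of CCL22 is not known here, so a background contribution was not told apart. None of 21 NF-kB and inflammatory cytokine genes passed in limma over all genes (4 at an unadjusted p under 0.05), and 1, the cytokine gene IL18 at 0.33, did adjusted over the list alone (median -0.065; camera adjusted p = 0.736). TNF was at -0.24 and NFKB1 at 0.21. The camera direction for this list was up while its median was below 0. None of 22 immediate early genes passed in limma (1 at an unadjusted p under 0.05), and 0 did adjusted over the list alone (median -0.064; camera adjusted p = 0.249).

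Stem and progenitor markers were slightly higher as a list. Of 24 markers 1 rose and 23 did not pass, with 1 adjusted over the list alone (median 0.089). The median was 0.14 in pair 1 and 0.028 in pair 2, at percentiles 95.4 and 82.9 of random lists matched on mean signal. Camera gave an adjusted p of 0.00601, and adjusted p = 0.721 with an estimated correlation. ANGPT1, the TIE2 ligand angiopoietin-1, rose by 0.34 (SE 0.098; limma adjusted p = 0.0246), while the cytokine receptor gene KIT was at 0.25 and the surface marker THY1 at -0.26, both without passing. The list median stood at percentile 94.1 of 10000 random lists matched on mean signal, and loess on signal left the median at 0.074 while the call ended (camera adjusted p = 0.129).

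Among markers of more mature blood cells HBB and KLF1 fell and CPA3 rose. Of 13 erythroid markers 2 fell and 11 did not pass, and adjusted over the list alone 1 rose and 2 fell (median -0.13; camera adjusted p = 0.117). Beta-globin, HBB, fell by 0.41 (SE 0.11) and the erythroid transcription factor gene KLF1 by 0.31 (SE 0.093), at limma adjusted p = 0.0109 and 0.0347. HBB changed by -0.20 in pair 1 and -0.62 in pair 2. Negative control probe sets of like signal, with 16 GC bases, changed by -0.36 and -0.21. A background contribution to the falls of HBB and KLF1 was not told apart here. The transferrin receptor gene TFRC was at 0.28 and passed over the list alone. Of 18 granulocyte precursor markers the mast cell protease gene CPA3 rose, by 0.33 (SE 0.093; limma adjusted p = 0.0216), and 17 did not pass, with 1 adjusted over the list alone (median -0.031; camera adjusted p = 0.661). No member passed in limma, over all genes or adjusted over the list alone, among 19 monocyte and macrophage markers (median -0.11; camera adjusted p = 0.161) or 13 megakaryocyte and platelet markers (median -0.0039, with the camera direction up; camera adjusted p = 0.715). The same held for 24 T, B and NK cell markers (median -0.11; camera adjusted p = 0.0702) and 14 endothelial markers (median -0.10; camera adjusted p = 0.292). At an unadjusted p under 0.05 these lists had 5, 1, 3 and 2 members. The monocyte genes LYZ and S100A9 were at 0.25 and -0.22, and the T cell gene CD3E at -0.26.

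Sterol biosynthesis genes were higher as a list. Of 19 genes 2 rose and 17 did not pass, and 5 rose adjusted over the list alone (median 0.12). HMGCS1, the HMG-CoA synthase at the head of the pathway, rose by 0.30 (SE 0.091) and the sterol demethylation enzyme gene MSMO1 by 0.29 (SE 0.093), at limma adjusted p = 0.0342 and 0.0487. Camera gave an adjusted p of 7.4e-04, and adjusted p = 0.721 with an estimated correlation. The list median stood at percentile 97.1 of the matched random lists. It was 0.22 in pair 1 and 0.036 in pair 2, at percentiles 99.5 and 86.65. The call ended after quantile normalization (median 0.14; camera adjusted p = 0.0683) and without the dimmest 50% of genes (median 0.0999; 0.0698). Without the block and with vehicle 1 or treated array 2 left out, the list median was 0.0037 and 0.060 (0.190 and 0.0637). Of 11 heat shock genes 0 passed in limma over all genes, 4 had an unadjusted p under 0.05, and the same number rose adjusted over the list alone, DNAJA1, HSP90AB1, HSP90AA1 and HSPH1, at 0.27, 0.25, 0.23 and 0.22. Their list median of 0.11 stood at percentile 74.1 of the matched lists, with a camera adjusted p of 0.0252 and adjusted p = 0.721 with an estimated correlation. The median was 0.20 in pair 1 and 0.024 in pair 2, at percentiles 88.7 and 38.3. Without the dimmest 30% of genes their camera adjusted p was 0.0572 (median 0.13). Without the block it was 0.102, and with vehicle 1 also left out the list median was -0.026. After loess the list median was 0.060 at a camera adjusted p of 0.387, with DNAJA1, HSP90AB1 and HSP90AA1 at 0.16, 0.040 and 0.11.

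Other stress, growth, adhesion and signalling lists gave few called genes. MDM2, the ubiquitin ligase of p53, rose by 0.33 (SE 0.092; limma adjusted p = 0.0183) as the 1 of 20 p53 and apoptosis genes that passed (1 adjusted over the list alone; camera adjusted p = 0.161). The DNA replication helicase gene MCM6 rose by 0.32 (SE 0.092; limma adjusted p = 0.0225) as the 1 of 29 cell cycle genes (1 adjusted over the list alone; camera adjusted p = 0.248). HSPA5, the endoplasmic reticulum chaperone BiP, rose by 0.32 (SE 0.094; limma adjusted p = 0.0274) as the 1 of 22 unfolded protein and integrated stress response genes. After loess HSPA5 was at 0.15 (SE 0.072) and after quantile normalization at 0.17, both without passing. Adjusted over the list alone 2 of these 22 rose and 1 fell (camera adjusted p = 0.0729). TXN, or thioredoxin, rose by 0.31 (SE 0.091; limma adjusted p = 0.0276) as the 1 of 17 oxidative stress and metallothionein genes, of which 5 rose adjusted over the list alone (camera adjusted p = 0.0649). TXN was at 0.20 after loess (SE 0.079) and after quantile normalization, without passing. Of 21 adhesion and homing genes the integrin gene ITGA4 and the "do not eat me" signal CD47 rose, both by 0.29, with 2 adjusted over the list alone (camera adjusted p = 0.103). None of 24 hypoxia and glycolysis genes passed, nor of 20 TGF-beta, Notch, Wnt and prostaglandin signalling genes, and 0 did adjusted over the list alone (camera adjusted p = 0.161 and 0.516), with 4 and 2 at an unadjusted p under 0.05 in limma.

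Control probe sets on the same arrays shifted with treatment as well. All 14 classes of background probe sets with 12 or more GC bases were lower on both treated arrays than on both vehicle arrays, with median changes of -0.24 in both pairs. The 8 classes with 10 or fewer GC bases had median changes of -0.0015 and -0.057. With each array centred on its median, the 14 classes kept median changes of -0.19 and -0.23. Poly-A spike-ins, bacterial RNAs added before labelling, changed by a mean of 0.49 in pair 1 and 0.13 in pair 2, and hybridisation controls by 0.21 and -0.082. Background levels ran from 2.31 to 12.3 with GC content, so no single detection limit applies to the genes.

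**Figure D3:**
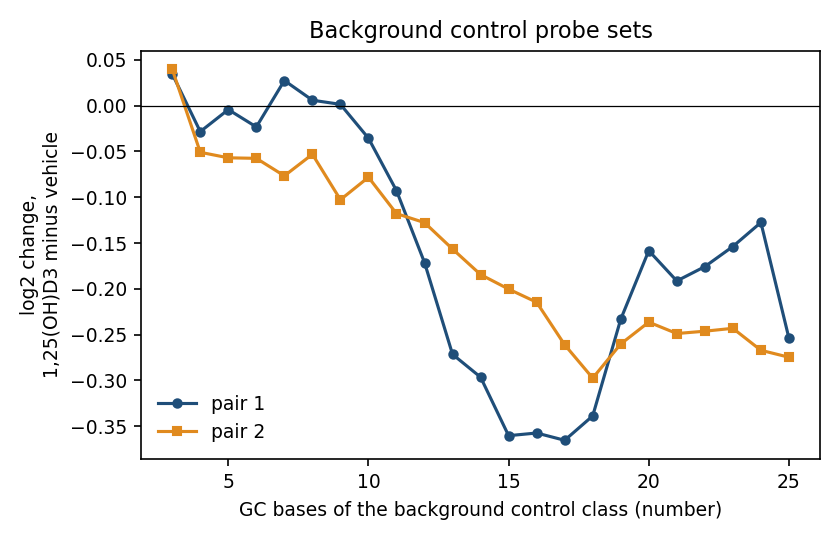
Log2 change of the 23 background control classes, 1,25(OH)D3 minus vehicle, against the number of GC bases in each class's probes, in pair 1 (circles) and pair 2 (squares). From 12 GC bases upward every class is below 0 in both pairs, with the largest falls at -0.37 in pair 1 and -0.30 in pair 2.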

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

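The tests on quantile normalization, RNA input, VDR targets, matched lists, the largest background fall beside the interferon list and genes of like signal were chosen after the results were seen, and those on GC-rich chromosomes and on the interferon level of vehicle arrays before. On the control probe sets, which lie outside the gene comparisons, 4 controls read higher on both treated arrays than on both vehicle arrays. These were the poly-A spike-ins dap, lys and thr, with mean changes of 0.20, 0.36 and 0.51, and the hybridisation control cre with 0.072. Chance alone would place 16.7% of controls that way, and 8 were examined. The 8 lie on the same 4 arrays and are not independent, so their count cannot be tested against that share.

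The first pattern is the shift shared by both pairs across genes. Quantile normalization left r between the pairs at 0.473, which argues against unequal signal distributions as its whole source. Genes on chromosomes 16, 17, 19 and 22, which are GC-rich, had lower changes than those on the GC-poor chromosomes 4, 5, 6 and 13, by a difference in medians of -0.058 as the mean of the pairs. The bootstrap intervals lay below 0 in pair 1 (-0.099 to -0.075) and in pair 2 (-0.035 to -0.025). Each was taken within 1 pair and so does not measure variation between arrays. A GC-dependent signal difference between the arrays may contribute. However, the untreated vehicle arrays of the 2 cord blood samples also differed, vehicle 2 minus vehicle 1, by -0.024 (-0.030 to -0.018). Less RNA in the treated preparations also stays open, since spike-ins exceeded hybridisation controls by 0.25 (0.28 and 0.21 in the pairs) and the amounts added are not known here. The test on known VDR targets could not tell, as it asked for a rise of the list or for no member higher in both pairs. Their median in blood cells was -0.070, with 9 members higher and 26 lower by mean change. In both pairs 6 were higher and 20 lower. These 35 genes are too few to carry a shift across 22411 genes.

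The second pattern is the lower signal of interferon-stimulated genes. The list median stood at percentile 0 of matched random lists in pair 1 and 0.02 in pair 2, which argues against a shift common to genes of like signal. Among matched lists moved to the largest fall of a background class (-0.37 and -0.30), the list's mean stood at percentile 0.1 in pair 1 (-0.49) and 100 in pair 2 (-0.058), so a GC-dependent difference is unlikely to be the whole source in pair 1 and stays open in pair 2. An unusually high interferon signal in the vehicle cells of pair 1, or a deviation of treated array 1, cannot be told apart from an effect of the hormone. The list was lower in vehicle 1 than in vehicle 2 (-0.90), which the rule set beforehand counted against a high signal in vehicle 1. The treated arrays differed too (-1.27), so the difference between the cord blood samples hides what that test was meant to show.

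The third pattern is the rise of CXCL8. The genes of like signal had median changes of -0.010 and -0.015, which argues against a shift common to them. Its change was at percentile 98.3 of these genes in pair 1 and 93.7 in pair 2, inside the central 95% there, so scatter among such genes may account for it. Loess on signal left the change at 0.31 (SE 0.090), against 0.30 (SE 0.093) before, and the call ended at an adjusted p of 0.0773 because the prior degrees of freedom became finite, at 19.3 (0.0174 with the same changes and SEs at infinite degrees of freedom). A response to the hormone stays open as a hypothesis.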

How the results depend on the processing

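Loess on signal, protein-coding genes alone and the same-sign rule were chosen after seeing the data, and the other alternatives beforehand. The cause was tested for the gene counts after quantile normalization and loess, and for no other change below except where fewer genes, fewer arrays or another threshold give it by construction. The counts of 485 higher and 306 lower genes became 0 and 0 without the replicate block, which leaves donor differences in the error, 16 and 11 after quantile normalization, 62 and 21 over all probe sets, and 163 and 68 after loess. The prior degrees of freedom, infinite in the first fit, were 12.5 after quantile normalization and 19.3 after loess. With the error taken wholly from the trend, a test chosen after seeing the data, these fits gave 1128 higher and 540 lower genes and 1422 higher and 437 lower. The smaller counts therefore came with the estimate of error. Finite prior degrees of freedom mean that genes of like signal differ in spread, which an error from the trend alone leaves out. The larger counts are thus no support for the first calls. At an adjusted p under 0.1 they were 980 and 696, and tested against a fold of 1.2 they were 4 and 0. Lower genes numbered 199 and 188 without the dimmest 30% and 50%, and 155 with arrays centred, and 73.0%, 75.6% and 79.7% of calls were then higher, as were 70.6% after loess and 74.7% over all probe sets.

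The 13 genes at an unadjusted p under 0.05 and 1.5-fold became 7 without the block, 8 and 5 without the dimmest 30% and 50%, 138 over all probe sets, 1 among protein-coding genes, 1469 at a fold of 1.2 and 1 at a fold of 2. Agreement of the pairs, r = 0.499, was 0.602 and 0.659 without the dimmest 30% and 50%, 0.619 among protein-coding genes and 0.343 over all probe sets. The 4 called lists became 2 without the block, 1 without the dimmest 50%, 1 after quantile normalization, 2 after loess, 6 over all probe sets, 6 among protein-coding genes, and 0 both with an estimated correlation and in fry. Quantile normalization ended the calls of sterol biosynthesis genes (camera adjusted p = 0.0683), stem and progenitor markers (0.148) and heat shock genes (0.396). Their medians went from 0.12, 0.089 and 0.11 to 0.14, 0.082 and 0.064. Removal of the dimmest 50% ended the same calls (0.0698, 0.0897 and 0.132), with medians of 0.0999, 0.093 and 0.13. The median of the VDR targets of blood cells stayed below 0 under every alternative run and was uncalled in each that gave a test. Its ends, -0.11 and -0.034, are the single pairs, which give no test.

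Leaving out 1 array was run without the block, since its partner then adds nothing to a blocked fit, and the lone array of its group was assumed to vary like the others. These fits set a mean of both cord blood samples against 1 of them, so donor differences enter the change by construction. In limma they gave 0 to 2 higher genes, 0 to 0 lower, 552 to 4655 at an unadjusted p under 0.05, 16 to 139 at 1.5-fold and 4 to 14 lists. Over these fits and the single pairs, 11 list medians changed sign. They ran from -0.82 to 0.37 for interferon-stimulated genes, -0.29 to 0.31 for unfolded protein and integrated stress response, -0.29 to 0.17 for megakaryocyte and platelet markers, -0.026 to 0.35 for heat shock, -0.16 to 0.057 for NF-kB, -0.11 to 0.11 for cell cycle and -0.29 to 0.13 for immediate early genes. Smaller ranges were -0.026 to 0.013 for vitamin D receptor and metabolism, -0.054 to 0.056 for p53 and apoptosis, -0.031 to 0.088 for oxidative stress and -0.023 to 0.088 for adhesion and homing genes. The 9 called genes that changed sign ran from -0.59 to 1.195 (CXCL8), -0.59 to 1.24 (HSPA5), -1.55 to 0.49 (RSAD2), -1.55 to 0.66 (IFIT3), -1.35 to 0.38 (MX1), -1.13 to 0.20 (OASL), -1.66 to 0.47 (CXCL10), -0.13 to 0.79 (CPA3) and -0.064 to 0.65 (ITGA4). A further 14 named genes that had not passed changed sign as well, among them CYP24A1, CD14, KIT, LYZ and TNF. Sterol biosynthesis genes kept their sign, but their call ended without vehicle 1 (median 0.0037) and without treated array 2 (0.060). A single pair leaves no residual degree of freedom, so counts have no value there. Background levels that rise with GC content limit what dim signals show.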

Other observations

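The classes in this part were chosen after their values were seen, and their tests run across genes, which are not independent replicates. Several classes of small RNA genes stood out among the calls. Of 42 genes of the MIR548 family, microRNA genes derived from a transposable element, 22 rose and 0 fell, with median changes of 0.43 in pair 1 and 0.17 in pair 2 (Fisher's exact test for rises against all other genes, adjusted p = 4.4e-25). Of 238 snoRNA genes, guides of RNA modification, 32 rose and 1 fell (adjusted p = 1.0e-15 by the exact test). Of 213 copies named after spliceosomal small nuclear RNAs 29 rose and 3 fell (adjusted p = 1.6e-14 by the exact test). Other microRNA genes went the opposite way, with 19 higher and 82 lower of 999 (adjusted p for falls 6.7e-40 by the exact test). Of 489 copies named after 5S ribosomal RNA 18 rose and 13 fell (adjusted p = 0.0497 for each direction), and their median change of -0.014 became 0.037 after loess. The other medians here kept their sign under quantile normalization, median centring and loess. Members of these families resemble each other closely and their probe sets can share probes, so the counts are not of independent genes. Whether these probe sets report the small RNAs or longer transcripts that contain them was not checked here.

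Olfactory receptor genes, the odour sensors of the nose, numbered 359 with 0 higher and 20 lower (adjusted p for falls 4.2e-07 by the exact test), and a median change of -0.086 that became -0.021 after loess. Ribosomal protein genes had medians of 0.26 and 0.11 in the pairs, with 3 of 55 called higher, and a median of 0.19 that became 0.070 after loess. With treatment as a block, limma called 1094 genes between replicate 2 and replicate 1, against 791 for treatment and 3 with the labels of pair 2 exchanged. With 2 arrays per group such exchanges are too few to judge chance. Exchanging the labels of pair 2 also turns what the pairs share into error, whatever its source. A low count there follows from the agreement of the pairs.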
